A study of Mus musculus with 2 samples.

How the data were processed

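MicroRNA sequencing libraries from mouse cerebral cortex (strain B6NCrl, described as wild-type female controls) were analysed. The series holds 1 group of 2 libraries, which the labels number as biological replicates 1 and 2. Each has its own tissue sample record, but both cite the same donor record, and the sex and age fields read as not collected. Whether the libraries came from separate animals is therefore not stated, and the spread between them can be technical in part. With 1 group there was no treatment, genotype or tissue to compare. The comparisons made were between miRNA genes and gene lists within the tissue, and between the 2 libraries.

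The authors deposited 1 count table per library. Its values are raw read counts per annotated miRNA gene, not normalized, in 3 columns (either strand, 1 strand, and the other strand). Per the labels and the deposited readme text, the tables use the mm10 assembly and the M21 annotation. The labels give a size limit on the RNA and cite a document on adapter trimming for each library, a different one for each, so trimming and replicate cannot be separated. The aligner, the counter and their versions are not given in the sources used here. Each table starts with 4 summary lines that name no gene (unmapped reads, reads placed at several loci, uniquely placed reads outside genes, and ambiguous reads). These were left out of library sizes and tests, and their shares are given with the results. In each library, each of the 3 columns with its own values for reads outside genes and ambiguous reads summed to the same number of uniquely placed reads (4888589 in replicate 1 and 7499592 in replicate 2). Reads placed at several loci are thus in no gene's count.

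All 2202 gene identifiers in the tables matched GENCODE M21, which lists 2207 miRNA genes. Coordinates (mm10, counted from 1) and host genes were taken from it, and precursor GC content from its sequences, available for all 2202 genes. The sense column was taken as the stranded column with the larger total in both libraries. The deposited counts were scaled to CPM, the count of a gene relative to the total over all gene lines of its library. Genes were called detected at 2 CPM or more in both libraries. Values are given as mean ± SD over 2 libraries, and shares of single libraries with 95% Wilson intervals. Reads carry no molecular identifiers in these tables, so intervals and floors (3 counts) cover counting error only.

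Pearson's r on log2(CPM + 1) and Spearman's rho between the libraries were computed across genes, which are not independent replicates, with the SD of 1000 bootstrap resamples of genes. The biological coefficient of variation (BCV) was the square root of edgeR's common dispersion in a model with an intercept only, after TMM normalization, with 100 bootstrap resamples. The counts of each detected gene in the 2 libraries were compared by an exact two-sided binomial test given TMM-scaled library sizes, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio of at least 2. This test compares 2 libraries and their counting error, not conditions. Log2 ratios are replicate 2 over replicate 1, with 0.5 counts added to each count and exact 95% counting intervals. The median log2 ratio of the detected genes was -0.03 with TMM and -0.16 with library totals, and ratios are reported with TMM.

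Each list's summed share of counts was computed, and its median CPM was placed among 10000 random lists of the same size from all genes. Its median log2 ratio was placed among 10000 random lists matched on mean expression (10 bins of equal gene number), for lists with at least 3 members at a mean of 2 CPM or more. These percentiles describe these libraries and are not tests over animals. A percentile under 2.5 or over 97.5 was taken as outside the random lists.

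The binomial test was tested on simulated counts for the 438 detected genes. At an adjusted p under 0.05 alone, without the ratio limit, it recovered 172 of 200 genes changed by 2 times and 192 of 200 changed by 4 times. In either case 7 of 238 unchanged genes passed. These simulated counts held counting error only, at the true library scale. They do not cover the ratio limit, TMM or spread beyond counting error. A simulated BCV of 0.2 was estimated as 0.209 and one of 0.4 as 0.398.

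Before the data were examined, 20 lists of miRNA genes were fixed. They were neuron-enriched, Mir23 with Mir29 clusters (abundant in glia), oligodendrocyte, microglia and leukocyte, red blood cell, vascular, choroid plexus and ependyma, muscle, liver and pancreas, epithelium, the Mir183 cluster of sensory organs, embryonic stem cell, Hox cluster, testis-enriched X-linked, the let-7, Mir30, Mir181 and Mir26 families, the Dlk1-Dio3 cluster, and the Mir17 cluster with its paralogs. The genes named were fixed by a rule at the same time. They were the 20 of highest mean CPM, the 3 highest members of each list, and the 5 called genes with the largest ratio in each direction among those at a mean of 100 CPM or more. Not every gene picked by the rule is named below, as in the Mir30 and Mir181 families and the Mir17 cluster with its paralogs. Other genes named were chosen after their values were seen. Genes whose symbol carries a copy number (Mir124a-1, for example) were taken, by symbol alone, to encode an identical mature sequence at several loci. The tables hold 142 of them. Mature sequences were not compared, but all 142 share a run of 18 nt with another precursor.

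The alternatives tried were the unstranded column, other detection minimums and pseudocounts, DESeq2 size factors and library totals in place of TMM, a ratio of 1.5, leaving out numbered copies or the most abundant gene, random lists from genes with a count, thinning the deeper library to the depth of the shallower one, and each replicate alone. Removing a lowess trend with GC content (fraction 0.66), leaving out 9 genes, and defining copies by a shared run of 18 nt were chosen after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.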

Results

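Small RNA from wild-type mouse cerebral cortex (strain B6NCrl) was sequenced in 2 libraries, which the labels call biological replicates without stating separate animals, to profile microRNAs (miRNAs), short RNAs that repress messenger RNAs carrying matching sites. Replicate 1 held 12506469 reads and replicate 2 held 18276311. Of these, 4429633 in replicate 1 and 6985784 in replicate 2 were counted in the sense direction of an annotated miRNA gene. The limit that a count of 0 allows was 0.677 CPM in replicate 1 and 0.429 CPM in replicate 2. Reads placed at several loci, which enter no gene's count, made up 43.9% of the reads of replicate 1 (95% Wilson interval 43.8 to 43.9) and 47.9% of those of replicate 2 (47.9 to 47.9). Unmapped reads made up 17.0% and 11.1%. In the either-strand column, uniquely placed reads outside genes made up 3.67% and 2.81%, and ambiguous reads 1.74% and 2.15%. Those ambiguous reads, 217526 and 393132, equal or nearly equal the 217526 and 393133 opposite-strand counts in genes that overlap another on the opposite strand. The sense counts thus already hold nearly all of them, so the shares of ambiguous and sense reads overlap. All abundances and ranks below are among uniquely placed reads.

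The first question was which miRNA genes make up the cortical profile. A single gene, Mir139, held 19.8% ± 2.34 of the counts (SD, n = 2). Mirlet7b, of the let-7 family that accumulates as tissues mature, followed with 5.31% ± 0.202. Mir132, a neuronal miRNA induced by activity, held 5.21% ± 1.34, and Mir127, from the imprinted Dlk1-Dio3 cluster, held 4.48% ± 0.221. The 10 most abundant genes together held 52.3% ± 3.64 of the counts and the 100 most abundant held 95.9% ± 0.0701. Of 2202 genes, 438 were detected at 2 CPM or more in both libraries, 185 at 100 CPM or more and 18 at 10000 CPM or more, while 1415 had no count in either library.

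Mir139 lies in an intron of Pde2a on chromosome 7 (101475376 to 101475443, mm10) and was counted at 197523 ± 23401 CPM (SD, n = 2). Mirlet7b lies in an exon of the noncoding gene Lncppara on chromosome 15 (85707319 to 85707403). Mir132 lies in an intron of 1700016P03Rik on chromosome 11 (75173682 to 75173747) at 52078 ± 13446 CPM. Its neighbour Mir212 (75173388 to 75173478), also in an intron of that gene, was counted at 1741 ± 394 CPM. Mir127 lies on chromosome 12 (109592846 to 109592915) outside annotated hosts. Mir744, in an intron of Map2k4 on chromosome 11 (65734733 to 65734832), ranked after Mir127 at 38174 ± 21093 CPM, with 53089 CPM in replicate 1 and 23259 CPM in replicate 2. The let-7 genes Mirlet7i (36192 ± 11205 CPM), Mirlet7g (29922 ± 10015 CPM), Mirlet7d (28197 ± 200.3 CPM) and Mirlet7e (21078 ± 2256 CPM) were also among the first 20. Mir125a (16452 ± 1316 CPM) was among them too and lies beside Mirlet7e in Spaca6 on chromosome 17. The others were Mir23b, Mir770, Mir149, Mir652, Mir22, Mir30d, Mir330, Mir29a, Mir598 and Mir23a, from 22443 ± 1559 CPM for Mir23b to 10194 ± 3226 CPM for Mir23a.

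Gene families and clusters took large shares. The let-7 family held 17.1% ± 2.21 of the counts (SD, n = 2), with 12 of its 12 measured members detected. The Dlk1-Dio3 cluster, a maternally expressed imprinted array, held 13.6% ± 1.29. Its 57 measured members lie within 184 kb of chromosome 12 (109563692 to 109747960), and 50 of them were detected. Levels within the array ran from 44811 CPM for Mir127 down to 0 counts for 4 members, with 18 members at 1000 CPM or more. After Mir127 came Mir770, in an exon of Meg3, at 20193 ± 8368 CPM and Mir433 at 10173 ± 4160 CPM. The Mir30 family held 2.21% ± 0.619, the Mir181 family 0.348% ± 0.0298 (0.174% with numbered copies left out), the Mir17 cluster with its paralogs 0.278% ± 0.0156 and the Mir26 family 0.262% ± 0.131, with 0.169% in replicate 1 and 0.354% in replicate 2.

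The neuron-enriched list held 10.2% ± 1.11 of the counts (SD, n = 2), and 29 of its 33 genes were detected. Its leading members were Mir132, Mir598 in an intron of Xkr6 (11249 ± 1807 CPM) and Mir128-1 in an intron of R3hdm1 (7392 ± 584 CPM). Other numbered copies of the list ran from high to below the detection minimum. Mir138-1 was counted at 4762 ± 166 CPM and Mir129-2 at 2946 ± 675 CPM. The 3 Mir124a genes, which encode a miRNA abundant in neurons, had 17 counts together in replicate 1 and 31 in replicate 2 (4.14 ± 0.424 CPM), and the 3 Mir9 genes had 72 and 617. Over the members of all 20 lists, the 52 numbered copies had a median of 40.9 CPM and the other 181 genes one of 57.4 CPM. Split by a shared run of 18 nt, the medians were 45.6 and 56.9 CPM. Over the neuron, let-7, Mir30, Mir181, Mir26, glial and oligodendrocyte lists alone, a grouping that was not planned, they were 115 CPM for 38 numbered copies and 1741 CPM for 37 others. These differences were not tested. Reads placed at several loci are missing from all of these values. Those of numbered copies, Mir128-1 among them, are therefore not levels of a mature miRNA shared between loci.

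Lists of glial and vascular miRNAs followed. The Mir23 and Mir29 clusters, abundant in astrocytes and other non-neuronal cells, held 5.18% ± 0.244 of the counts (SD, n = 2), with 10 of 10 genes detected and Mir23b, Mir29a and Mir23a highest. The oligodendrocyte list held 0.748% ± 0.0524, led by Mir219a-2 (4968 ± 717 CPM) and Mir338 in an intron of Aatk (2502 ± 193 CPM). Mir219a-2, a numbered copy, overlaps Mir219b on the opposite strand. The opposite-strand counts of Mir3065 (11687 and 16525) likewise equal the sense counts of Mir338. The unstranded column leaves the list 4.22e-05% of the counts. With numbered copies left out the list held 0.259%. The vascular list held 0.486% ± 0.0807, with the endothelial Mir126a, in an exon of Egfl7, at 2294 ± 924 CPM and the mural cell gene Mir143 at 2139 ± 108 CPM, and 0.271% with the unstranded column. The microglia and leukocyte list held 0.109% ± 0.0273, nearly all of it Mir150 (1022 ± 261 CPM), while Mir155 was at 56.9 ± 13.4 CPM and Mir223 at 6.65 ± 0.495 CPM. Only 5 of its 7 symbols matched a counted gene. Its symbol Mir146a matched none. The gene annotated as Mir146, at 449 CPM in replicate 1 and 660 CPM in replicate 2, is therefore missing from this share.

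The red blood cell list held 0.00168% ± 0.000496 of the counts (SD, n = 2) and 3.56e-05% with the unstranded column. Shares were low as well in the muscle list (0.00277% ± 0.000846), the Hox cluster list (0.0011% ± 0.000262) and the embryonic stem cell list (0.000304% ± 1.52e-05). Of the 10 muscle genes, 4 are numbered copies and 7 had no count in either library. Reads placed at several loci are missing, so the low muscle share does not show an absence of muscle RNA. The liver and pancreas list held 0.198% in replicate 1 and 0.0303% in replicate 2, and the choroid plexus and ependyma list 0.117% and 0.247%. The testis-enriched list had 0 counts in replicate 1 and 5 in replicate 2. The median CPM of the let-7, Dlk1-Dio3 and neuron lists lay at the 100th percentile of random lists from all genes. Since 1415 of 2202 genes had no count, other lists came near it too. The Mir17 cluster with its paralogs, at a median of 9.28 CPM, lay at the 99.97 percentile. With random lists from genes with a count, 12 of the 20 lists moved across the limits of the random lists.

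**Figure D1:**
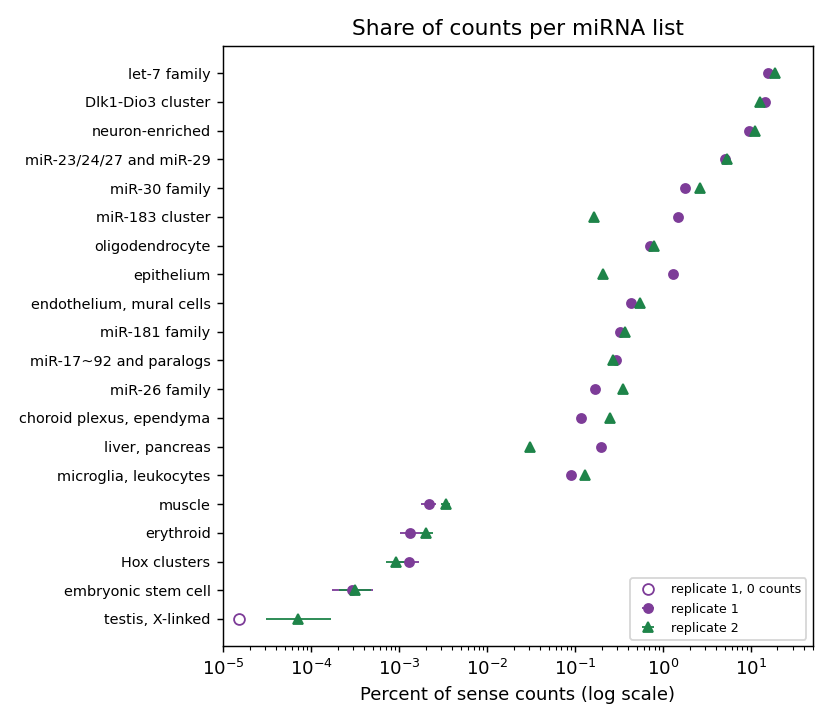
Percent of sense counts (log scale) in each of the 20 miRNA lists, with 1 symbol per library and 95% Wilson intervals; open symbols mark 0 counts. The let-7 family (17.1% on average) and Dlk1-Dio3 cluster (13.6%) hold the most, and the epithelium list (1.28% and 0.206%) and Mir183 cluster (1.47% and 0.163%) are set apart between the libraries.

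How far the 2 libraries give the same profile was examined next. Of 198 genes at a mean of 100 CPM or more, 37 were called different, 14 higher in replicate 1 and 23 higher in replicate 2. The Mir200 family and the Mir183 cluster were higher in replicate 1, and choroid plexus miRNAs were higher in replicate 2. Across the 438 detected genes, Pearson's r was 0.973 ± 0.0042 (bootstrap SD) and Spearman's rho was 0.965 ± 0.00522. The BCV was 0.412 ± 0.0247 (bootstrap SD), and 56.8% of genes were within 1.5 times of each other. The exact binomial test put 278 of 438 genes past counting error, and 77 were called at a ratio of at least 2, with 41 higher in replicate 2 and 36 higher in replicate 1. With library totals in place of TMM, 83 genes were called, with 29 higher in replicate 2 and 54 in replicate 1. A chi-square per degree of freedom of 681 over genes with a count set the libraries apart from a single library processed again in the same way. It cannot tell separate animals from 1 sample prepared or trimmed in different ways.

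**Figure D2:**
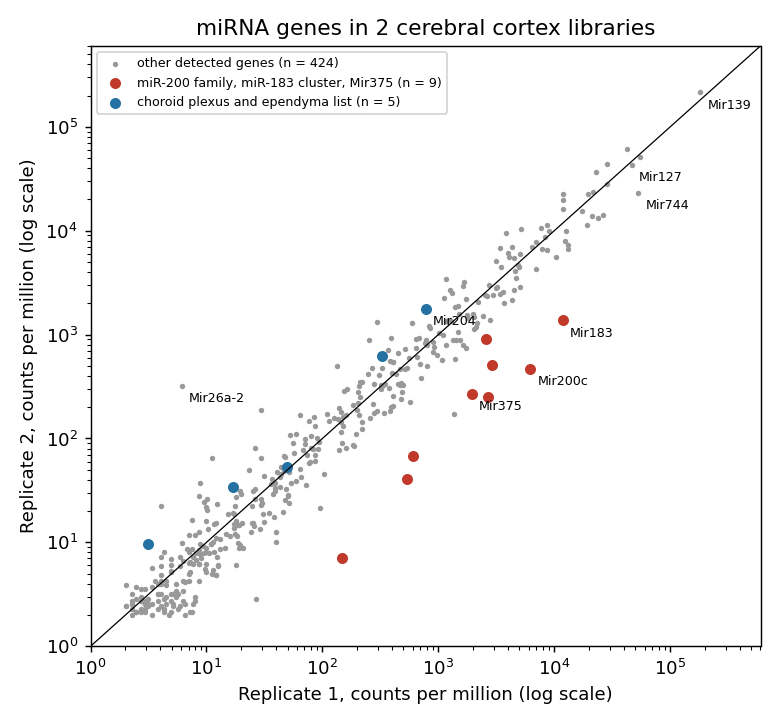
CPM (log scales) of each detected miRNA gene in replicate 1 against replicate 2, where the line marks equal values. The Mir200 family, Mir183 cluster and Mir375 lie below the line (Mir200c at 6184 and 470.0 CPM), and choroid plexus and ependyma genes lie above it (Mir204 at 778 and 1755 CPM).

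Epithelial miRNAs were higher in replicate 1. Of 7 genes in the epithelium list, 6 were called higher in replicate 1 (6 also adjusted over the list alone), and the median log2 ratio was -2.39, at the 0.01 percentile of matched random lists. Mir200c (chromosome 6, 124718322 to 124718390) had 27393 counts in replicate 1 and 3283 in replicate 2, a log2 ratio of -3.59 (exact interval -3.65 to -3.54). Its neighbour Mir141 had a log2 ratio of -3.60, and Mir200a, Mir429 and Mir200b, together on chromosome 4, had -3.01, -2.39 and -1.38. Mir205, a gene of stratified epithelium, had 80 and 42 counts and was called at -1.45. Mir203, a skin miRNA, was the exception, with a log2 ratio of 0.66 and no call.

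The Mir183 cluster, which is abundant in sensory organs, was also higher in replicate 1. All 3 of its genes were called higher in replicate 1 (3 also adjusted over the list alone), with a median log2 ratio of -3.29 at the 0.035 percentile. Mir183 (chromosome 6, 30169668 to 30169737) had 52574 and 9549 counts, a log2 ratio of -2.99, Mir182 had -3.29 and Mir96 had -4.24. In the liver and pancreas list, 1 of 3 tested genes was called, the endocrine gene Mir375, with 8627 counts in replicate 1 and 1869 in replicate 2 (log2 ratio -2.74), while the liver gene Mir122 had 112 and 219. The Mir200 family, the Mir183 cluster and Mir375, 9 genes, held 2.94% of the counts of replicate 1 and 0.388% of those of replicate 2. Outside them, Mir185, in an intron of Tango2, had a log2 ratio of -2.86, and Mir744 was called at -1.07. That of Mir744 was -0.94 with the GC trend removed and -0.97 with no filter on low counts, both short of a call.

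Choroid plexus and ependymal miRNAs went the other way. Of the 5 tested genes, 4 were called higher in replicate 2 (4 also adjusted over the list alone), with a median log2 ratio of 1.13 at the 99.5 percentile. Mir204, in an intron of Trpm3, had 3447 and 12258 counts and a ratio of 2.46 times, Mir211, in an intron of Trpm1, had a log2 ratio of 1.69 on 14 and 67 counts, Mir34b had 1.13 and Mir34c had 1.06. Mir449a, a gene of ciliated cells, was not called (0.22). With the GC trend removed 2 genes of the list were called, as Mir34b (0.94) and Mir34c (0.64) fell short of a ratio of 2, and with library totals 3 were called, without Mir34c (0.93). The Mir26 family also lay outside the random lists, with 3 of 3 genes called higher in replicate 2 (3 also adjusted over the list alone) and a median of 1.06 at the 98.9 percentile. Mir26a-2, a numbered copy like Mir26a-1, had 27 counts in replicate 1 and 2238 in replicate 2. Its log2 ratio was 5.82 (exact interval 5.30 to 6.45), while Mir26b had 1.06. With library totals only 1 of the 3, Mir26a-2, was called, since Mir26b had 0.94 and Mir26a-1 had 0.88. Mir26a-1 also fell short with the unstranded column and with the deeper library thinned. Among called genes at a mean of 100 CPM or more, the largest ratios toward replicate 2 after Mir26a-2 were those of 4 genes. They were Snord43, whose symbol is that of a small nucleolar RNA, at 2.79, Mir1839 at 2.29, Mir21a at 2.02 and Mir1298, in an intron of Htr2c, at 1.93.

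The medians of the remaining lists lay within the random lists. Of the genes named below as called, Mir9-1, Mir9-3, Mir135a-2, Mir7-2, Mirlet7f-1, Mirlet7f-2, Mir24-1, Mir181a-1, Mir92-2 and Mir129-2 are numbered copies. Their counts lack reads placed at several loci, so their ratios need not hold for the mature miRNA as a whole. In the neuron-enriched list, 3 of 29 tested genes were called higher in replicate 2 (Mir9-1, Mir9-3 and Mir135a-2) and 2 higher in replicate 1 (Mir153 and Mir7-2), with the same counts adjusted over the list alone, and the median log2 ratio was 0.23 at the 91.5 percentile. Mir7-2 (-1.02) was not called with DESeq2 size factors (-0.99), without a filter (-0.92) or with the deeper library thinned (-0.99), nor Mir135a-2 with the GC trend removed (0.90). Mir9-1 was not detected in the unstranded column, nor were Mir380, Mirlet7f-1 and Mir24-1 of the lists that follow. In the Dlk1-Dio3 cluster, 4 of 50 genes were called, all higher in replicate 2 (Mir379, Mir380, Mir411 and Mir496a), with a median of 0.03 that was -0.10 with library totals. With library totals 2 of its genes were called in each direction, without Mir411 and Mir496a and with Mir3070b (-1.10) and Mir370 (-1.02) toward replicate 1, and with the GC trend removed 1 in each, with Mir380 alone of these 4 and Mir381 (-1.09) toward replicate 1. In the let-7 family 3 of 12 genes were called higher in replicate 2 (Mirlet7f-1, Mirlet7f-2 and Mir98), and the median of 0.56 lay at the 96.7 percentile and was 0.23 with the unstranded column. With the GC trend removed 1 let-7 gene was called, without Mirlet7f-1 (0.79) and Mir98 (0.76), and Mir98 also lost its call with library totals (0.94). In the Mir23 and Mir29 clusters, 1 of 10 genes was called (Mir24-1, higher in replicate 2), and the median of 0.50 lay at the 93.2 percentile and was 0.14 with the GC trend removed. In the Mir181 family 1 of 6 genes was called (Mir181a-1, higher in replicate 2, at 1.02), which fell to 0.66 with the GC trend removed and 0.90 with library totals, short of a call. Among the Mir17 cluster and its paralogs 1 of 10 genes was called (Mir92-2, higher in replicate 1). None of the 3 tested oligodendrocyte genes, 3 vascular genes, 4 microglia and leukocyte genes or 6 Mir30 genes was called. At a ratio of 1.5, 8 neuron genes were called higher in replicate 2 and 2 higher in replicate 1. The Dlk1-Dio3 cluster then had 9 and 8, the let-7 family 6 and 0, and the Mir30 family 3 and 1. The Mir23 and Mir29 clusters had 3 and 0, the microglia and leukocyte list 2 and 0. The vascular and muscle lists had 1 and 0 each. In the epithelium list, Mir203 was then called toward replicate 2. At a ratio of 2, alternatives added single calls toward replicate 2. These were Mir126a with DESeq2 size factors (1.00, from 0.97) and without a filter (1.07), and Mir451a (2.72) and Mir499 (1.94) without a filter. Mir150 (1.02, from 0.65) and Mir27a (1.03, from 0.77) were added with the GC trend removed. Toward replicate 1, Mir129-2 was added with the unstranded column (-1.29, from -0.35), and Mir3070b with the deeper library thinned (-1.20, from -0.98). Of the 15 lists tested, 4 lay outside the random lists, and 5 did with the GC trend removed, when let-7 was added.

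The ratio between the libraries also varied with the base composition of the precursor. Across the 438 genes, which are not independent replicates, Spearman's rho between the log2 ratio and GC content was -0.453. The 110 genes lowest in GC (at most 46.1%) had a median log2 ratio of 0.44 and the 110 highest (at least 59.4%) one of -0.47. With the trend removed, 56 genes were called, 27 higher in replicate 2 and 29 higher in replicate 1, and the medians of the epithelium list and the Mir183 cluster were -2.51 and -3.47.

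**Figure D3:**
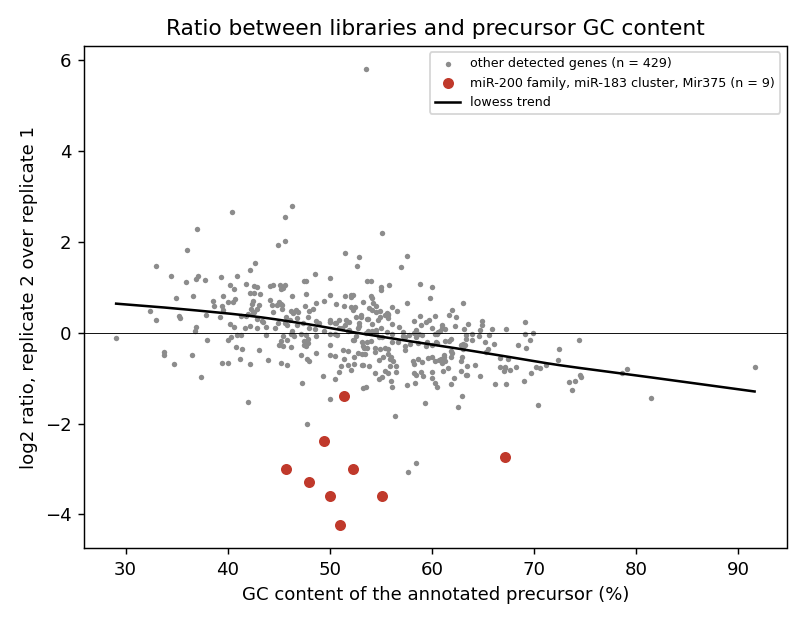
Log2 ratio of replicate 2 over replicate 1 for each detected miRNA gene against the GC content (%) of its annotated precursor, with a lowess trend. Ratios fall as GC content rises (Spearman's rho -0.453), and the Mir200 family, Mir183 cluster and Mir375 lie under the trend.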

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

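Reads placed at several loci and counts on the opposite strand were above the limit that a count of 0 allows. Reads placed at several loci made up 43.9% of replicate 1 and 47.9% of replicate 2. Counts on the opposite strand were 4.68% of stranded counts in replicate 1 and 5.33% in replicate 2. Of these, 99.9% in either library fell in the 64 genes that overlap another annotated gene on the opposite strand, such as Mir219b opposite Mir219a-2. Mir219b had 19759 and 38247 such counts, against 19759 and 38249 sense counts of Mir219a-2. These are thus sense reads of the partner counted again, not a separate signal. Only 148 and 212 counts fell elsewhere.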

How the results depend on the processing

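The GC trend, the 9 genes left out and the 18-nt definition were chosen after seeing the data. Of the alternative values for the main results, 54 stayed within their spread, or within 1.5 times for counts of genes, and 15 moved. For the other results 135 stayed and 32 moved. List medians changed direction in places, such as that of the Dlk1-Dio3 cluster, from 0.03 to -0.10 with library totals. Called genes were followed only if in a list or at a mean of 100 CPM or more. None of those changed direction where it was tested. For shares the spread is the SD of the 2 libraries, and either library alone always lies within it. Those single-library values were bound to stay, among them 17 shares of other results with each replicate left out. They are no sign of stability. With any count in both libraries, 666 genes were detected. For r and rho, all genes with a count gave 0.983 and 0.950, a minimum of 10 CPM 0.961 and 0.956, and leaving out numbered copies 0.977 and 0.970. The BCV was 0.364 without the 9 genes. At a ratio of 1.5, 169 genes were called, since more genes pass a lower ratio. Without Mir139 in the total, shares rose by construction, to 12.8% for the neuron list, 21.4% for let-7 and 17.0% for Dlk1-Dio3. The neuron share without numbered copies was 8.26%, since its copies left the sum. Numbered copies held 2.83% with the unstranded column, which loses genes with a partner on the opposite strand, and precursors sharing 18 nt held 21.9%. For the other moves the cause was not tested. Replicate 1 alone gave 477 detected genes and 49.8% in the first 10 genes, and replicate 2 alone 451 and 54.9%. No paired analysis was possible because there is 1 group. Depth limits the ratios of genes near 2 CPM, and a count of 0 allows up to 0.677 CPM in replicate 1 and 0.429 CPM in replicate 2.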

Other observations

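The tests of skin or ciliated epithelium, of called genes among numbered copies and of a shared primary transcript were chosen only after the result was seen, the first of them in place of a test on Mir203 and Mir205 alone whose values had been read.

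The Mir200 family, the Mir183 cluster and Mir375 were higher in replicate 1, and GC content, a stray epithelium and an endocrine tissue were weighed as sources. With the GC trend removed their median log2 ratio was -3.25, which argues against this trend as the whole cause. Removing it could shift these genes little, since their median GC content was 50.9%, against 53.2% over detected genes. Skin or ciliated epithelium would raise Mir203, Mir205, Mir34b, Mir34c and Mir449a, whose median was 0.66 toward replicate 2. That median could not point toward replicate 1, since 3 of these 5 genes, shared with choroid and ependyma, had ratios toward replicate 2. Mir203 (0.66) and Mir205 (-1.45) pointed opposite ways. These values do not decide on skin or ciliated epithelium. Endocrine tissue rich in Mir7 genes cannot be told apart. Mir7b (log2 ratio 0.46) is abundant in cortex at 2190 CPM in replicate 2, above Mir375 at 268 CPM, and would hide a small share. Mir7-2 (188 and 85.2 CPM) was called higher in replicate 1 at -1.02. With DESeq2 size factors its ratio hardly moved, to -0.99, but fell just short of a call. Other tissue carried over at dissection and the trimming that differs between the libraries stay open and were not tested, and the design, with 1 group, names no biological difference to set against them.

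The spread between the libraries exceeded counting error, with a BCV of 0.412. Base composition may account for part of it: rho with precursor GC was -0.453 over all detected genes and -0.465 with 1 value per cluster, and the trend removed 12.8% of the variance of the log2 ratio. The typical numbered copy did not differ more than other genes, with a median absolute log2 ratio at the 5.74 percentile of matched lists and at the 3.80 percentile of lists of other detected genes. Large ratios were more frequent among copies, with 14 of 45 called against 63 of 393 other genes (99.7 percentile of matched lists, and 13 of 44 at the 99.1 percentile without Mir26a-2), so reads shared between copies may add to the largest differences. The trimming cited for each library stays open and was not tested.

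Genes of 1 cluster (within 10 kb) could share their ratio through a common primary transcript. The intraclass correlation over 41 clusters was 0.585, and 0 of 1000 shuffles were as high. Without the 9 genes it was 0.0432, and 289 of 1000 shuffles were as high, and with numbered copies also left out it was 0.0222 (372 of 1000). Without the 9 genes and the Dlk1-Dio3 cluster it was -0.0764, and 712 of 1000 shuffles were as high. Outside the 9 genes these values give no sign of a shared ratio, and they do not exclude one.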
